A study of Homo sapiens with 12 samples.

How the data were processed

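RNA was sequenced from 12 cultures of THP-1, an established human cell line from an acute monocytic leukaemia, in 4 groups of 3 libraries. Per the labels, messenger RNA was captured on oligo-dT beads, fragmented, copied into cDNA and amplified by PCR. The values were placed on the human genome build hg38, per the submitters' processing notes, and the aligner, the counting tool, its strand setting and the gene annotation are not given in the sources used here. The authors deposited 3 tables of 78932 genes with Ensembl identifiers, of which 42745 carry a symbol. The first deposited table holds estimated counts, since 29.3% of its nonzero values are not whole within 0.005, and they are not scaled. The second deposited table holds TPM, with column sums of 999999 to 1000001. The third deposited table holds FPKM, with column sums of 722589 to 1132219, and within each library the ratio of FPKM to TPM differed between genes by a factor of at most 1.0004 where TPM was above 50. The columns name the groups in words that differ from the sample labels. The columns for NC carry the label's name, those for CEL name luspatercept in short, and those for LPS name pyroptosis, the model in the study design. The columns for CE say only that the cells were treated, and were matched as the remaining group. Replicates were matched by number, and 0 columns were left over. No source used here states this matching in full, and every value for CE rests on it.

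The estimated counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr over the 4 groups, which left 14065, and libraries were scaled with TMM factors. The 12 libraries entered a single quasi-likelihood fit in edgeR 4.0.16 with group as the term, and each pair of groups was tested with the two-sided F-test of that fit, adjusted by Benjamini and Hochberg over the tested genes. A gene is said to rise, fall or change where this adjusted p is under 0.05. The common dispersion was 0.0405, a biological coefficient of variation of 20.13%, with 8 residual and 2.93 prior degrees of freedom. Levels are CPM, counts scaled to the TMM-adjusted library size, given as mean ± SD over 3 libraries. Changes are log2 values ± an approximate standard error, the size of the change divided by the square root of its F statistic. It can be too small where a group has few counts. The prior count was 2 for log2 CPM in the principal components. The p-values measure only the spread between these samples, and intervals and floors on low counts cover counting error only. For a gene with 1 to 3 counts over a group, the ratio is given with an exact 95% interval, and for a group at 0 the ratio is a bound against a floor of 3 counts over the group.

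Lists of genes were tested with camera in limma 3.58.1, two-sided, with the inter-gene correlation preset at 0.01 and again with the correlation estimated for each list. There were 22 lists with 715 members, and the 21 with at least 5 tested members were tested and adjusted together. The lists cover pyroptosis and the inflammasome, NF-kB targets, interferon response, TLR4 signalling, calcineurin and NFAT, iron and heme, hypoxia and glycolysis, TGF-beta and activin signalling, cell cycle, protein stress, cholesterol synthesis, NRF2 targets, apoptosis and p53 targets, monocyte and macrophage markers, lysosome, oxidative phosphorylation, mitochondrially encoded transcripts, ribosomal proteins, replication-dependent histones, and markers of lymphocytes, of erythroid cells and megakaryocytes, and of fibroblasts, epithelium and endothelium. Genes changed by the model were compared with those changed by treatment, beside the number that independence would give. That number ignores that some genes are easier to call in any comparison, so an excess over it can arise without reversal. A simulation with no effect, repeated 20 times, gave the covariance and correlation that arise when both comparisons share the LPS libraries. It holds no changed genes, so it gives no number of opposite changes to expect beside real effects.

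Comparisons, tests, lists and the rule for naming genes were fixed before the data were examined. The rule names 10 core genes of pyroptosis and inflammation (IL1B, IL18, IL1A, NLRP3, CASP1, GSDMD, PYCARD, TNF, IL6 and CXCL8). It adds the 6 largest rises and the 6 largest falls among changed genes with a mean log2 CPM of at least 3 and no overlap between the groups. It also adds up to 4 members of each list, by smallest p, and 6 genes changed in opposite directions by the model and by treatment. Any other gene is said to be chosen after its values were seen.

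The labels' batch number equals the replicate number, so the numbers could pair the samples. This was checked on 7460 genes with a mean log2 CPM above 3. Of 18 same-numbered pairs of libraries, 6 had deviations from their group means that correlated with r over 0.1 (range -0.86 to 0.73, median -0.185), and 1 library correlated best with a library of its own number. The number was therefore left out of the fit and used as a block in an alternative. Within each group no library was a copy of another, with a chi-square per degree of freedom of 3.2 to 140.23 between replicates. Libraries of different groups were not compared in this way.

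Alternatives were upper quartile, relative log expression and library size scaling, no low-count filter, a stricter one (CPM over 1 and at least 10 counts in 3 libraries), DESeq2 1.42.0, limma-voom, and limma on log2 of TPM plus 1, TPM plus 0.1 and FPKM plus 1. A 2-fold threshold, an adjusted p under 0.01, fits of only the 6 libraries compared, the replicate block and leaving out each library in turn were also run. An offset for GC content (5 spline degrees of freedom, with a value for 94.18% of tested genes) and fits without pairs or triples of unusual libraries were added after the data were seen. GC content and coordinates came from GENCODE 29, on hg38, which holds 56411 of the gene identifiers. DESeq2's filtering gave no adjusted p for 45 genes in each comparison with LPS or NC, and for 1954 in CEL vs CE.

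The procedure was tested on simulated data with 50 genes changed at each size. For LPS vs NC, with 13576 genes, 28% were recovered at 1.41-fold, 64% at 2-fold, 80% at 2.83-fold and 94% at 4-fold, and 13 unchanged genes were called. For CE vs LPS (13568 genes) the shares were 42%, 80%, 84% and 92%, with 9 unchanged genes called. For CEL vs LPS (13571 genes) they were 32%, 68%, 82% and 94%, with 6, and for CEL vs CE (13535 genes) 30%, 74%, 82% and 92%, with 13. These simulations changed few genes, as many up as down. In the real comparisons 23.61% (CEL vs CE) to 55.93% (CEL vs LPS) of tested genes changed, which moves the adjusted threshold and can affect the scaling. The shares and false calls therefore do not carry over to the real tests. Of 3 lists shifted by 0.5, 3 were called, and 0 of the other lists. The simulated genes were drawn independently of each other, so this check cannot show false calls from correlated list members. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3.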

Results

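Messenger RNA was measured in 12 libraries of THP-1 cells, a human monocytic leukaemia line, in 4 groups of 3. The NC group was untreated. The LPS group received LPS, a bacterial cell wall component that activates TLR4, and ATP, which opens the P2X7 channel, as a model of pyroptosis (inflammatory cell death). The CE group received the same with cyclosporin A, a calcineurin inhibitor, and eltrombopag, which binds iron. The CEL group received in addition luspatercept, a ligand trap made from the activin receptor IIB. Each library held 17737213 to 23183429 counts, and 21775 to 26123 genes had a count. In what follows a value with ± in log2 units is a change with the approximate standard error derived from its F statistic. There are n = 3 libraries per group, and CPM are means ± SD.

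The groups separated along the first principal component, which held 55.6% of the variance, and LPS alone stood apart on the second, which held 18.6%. NC lay at -109.8 to -102.5 on the first, LPS at -3.3 to -0.3, CE at 46.2 to 51.9 and CEL at 57.6 to 60.5. On the second, LPS lay lowest at -69.6 to -54.7, and CE 2, at -14.5, lay apart from CE 1 and CE 3 at 26.9 and 20.

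**Figure D1:**
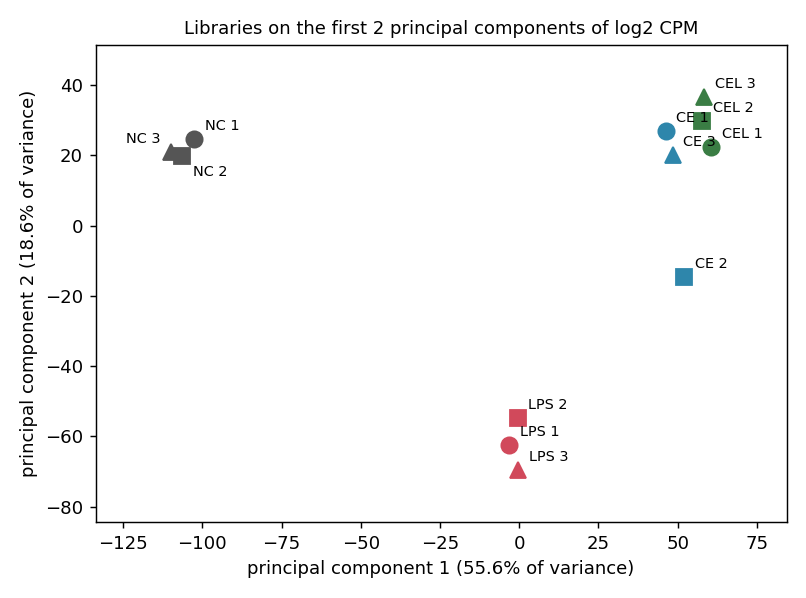
The 12 libraries by their first (horizontal, 55.6% of variance) and second (vertical, 18.6%) principal components of log2 CPM, with 1 point per library and colour by group. NC lies at or left of -102.5, LPS near 0 and low on the second axis, and CE and CEL lie between 46.2 and 60.5.

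The comparison of LPS with NC asks what the pyroptosis model does to THP-1 cells. IL1B, which encodes the cytokine matured by the inflammasome, rose 959-fold (9.91 ± 0.13), from 2.07 ± 0.251 to 1990 ± 106 CPM. IL1A, a related alarm cytokine, rose 534-fold, CXCL8, a neutrophil attractant, 454-fold, and TNF 30.1-fold, to 69.1 ± 1.66 CPM. IL6 had 218 counts in LPS and 1 in NC, in NC 1, a ratio of 215 with a counting interval of 38.2 to 8530. The inflammasome parts changed less, with CASP1, the protease that cleaves the IL1B precursor, up 2.73-fold (1.45 ± 0.06) and the sensor NLRP3 up 1.34-fold (0.42 ± 0.05). IL18, the other cytokine that caspase-1 matures, fell 2.01-fold to 12 ± 0.309 CPM. The adaptor PYCARD fell 1.5-fold (-0.58 ± 0.18, adjusted p = 0.0219), a call lost without NC 1, NC 2, LPS 2 or LPS 3 and with the GC offset (adjusted p 0.00351 to 0.304 over the alternatives). GSDMD, the pore protein of pyroptosis, was close to the detection limit at 0.383 ± 0.108 CPM in NC and 0.487 ± 0.386 in LPS, and no change was detectable (adjusted p = 0.779).

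These core genes lie, on hg38, on chromosome 2 (IL1A at 112773915 to 112784590 and IL1B at 112829751 to 112836903), chromosome 11 (CASP1 at 105025443 to 105035250 and IL18 at 112143251 to 112164117), chromosome 1 (NLRP3 at 247416156 to 247449108) and chromosome 8 (GSDMD at 143553207 to 143563062). TNF lies on chromosome 6 at 31575567 to 31578336, CXCL8 on chromosome 4 at 73740506 to 73743716, IL6 on chromosome 7 at 22725884 to 22732002 and PYCARD on chromosome 16 at 31201485 to 31203450.

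**Figure D2:**
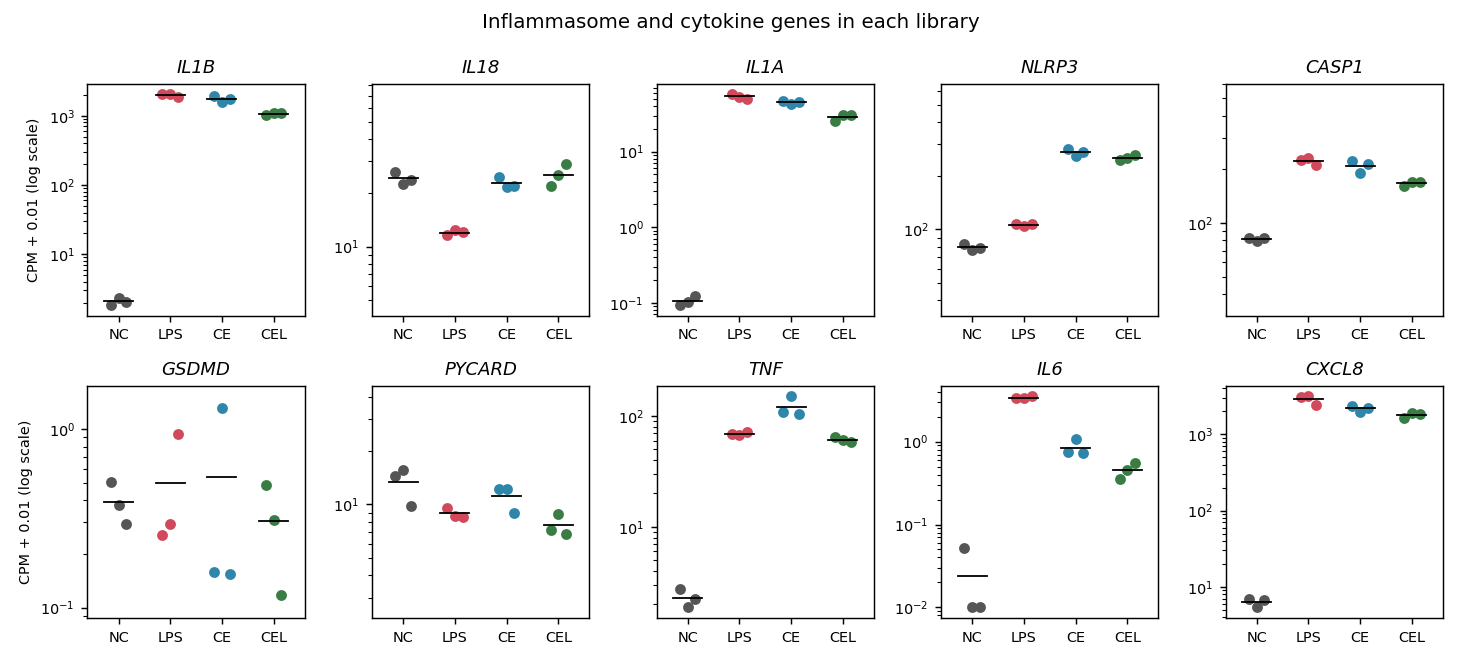
Levels of the 10 core genes of pyroptosis and inflammation (CPM + 0.01, log axis) in the 4 groups, with 1 point per library and a horizontal line at the group mean. IL1B goes from 2.07 CPM in NC to 1990 in LPS, 1740 in CE and 1080 in CEL, while NLRP3 is highest in CE (270) and CEL (253).

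Largest rises and falls are given among changed genes with a mean log2 CPM of at least 3 over the 12 libraries and no overlap between the groups. Beyond the core genes, the largest rises by this rule included IFI27, an interferon-induced mitochondrial protein (719-fold), CCL4L2 and CCL3, chemokines for monocytes and T cells whose reads can also match close paralogs (577-fold and 469-fold), and SLAMF7, a receptor on activated leukocytes, which reached 248 ± 8.24 CPM (487-fold). The largest falls by it were in CTSG, a granule protease of immature myeloid cells (18.3-fold, from 510 to 27.9 CPM), and KIT, the stem cell factor receptor (14.8-fold, from 225 ± 6.18 to 15.2 ± 1.36 CPM). TGM5, a transglutaminase, fell 8.46-fold, CLSTN2, a calsyntenin, 8.03-fold, NCALD, a calcium sensor, 7.98-fold, and DSG2, a desmosomal cadherin, 7.28-fold. In all, 3152 genes rose and 3306 fell, of which 1440 and 880 by at least 2-fold. Upper quartile scaling, which moved the median of all genes by -0.11, gave 2604 and 4387. With no low-count filter 3429 rose and 1956 fell, and limma gave 2070 and 893 on log2(TPM + 1) and 2179 and 772 on log2(TPM + 0.1), so the split depends on the method. The libraries of the groups did not overlap for 8791 genes (62.5%, against 10% by chance).

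The interferon list rose as a block, with 46 of 46 members higher (46 adjusted over the list alone) and a median change of 5.31 (adjusted p = 1.01e-109). The antiviral GTPases MX1 and MX2 rose 99.4-fold and 47.7-fold, and the interferon-induced gene IFIT3 73-fold. Among NF-kB targets, 41 were higher, 1 lower and 1 did not pass (43 adjusted over the list alone; median 4.91), including CCL4 (438-fold) and the pathway's own inhibitor NFKBIA (5.96-fold). The pyroptosis list had 20 members higher, 5 lower and 1 not passed (25 adjusted over the list alone; median 0.8, adjusted p = 2.73e-08), with the ATP-release channel PANX1 up 4.97-fold. In TLR4 signalling 11 were higher, 1 lower and 9 not passed (12 adjusted over the list alone). The LPS co-receptors CD14 and LY96 rose 49.9-fold and 16-fold, and the adaptor MYD88 rose 3.34-fold. Monocyte and macrophage markers rose, with 25 higher, 2 lower and 3 not passed (27 adjusted over the list alone; median 2.39). The calprotectin genes S100A8 and S100A9 rose 5.82-fold and 7.4-fold, while lysozyme (LYZ) fell 4.19-fold.

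Lysosomal genes also rose, 19 higher, 3 lower and 8 not passed (22 adjusted over the list alone; adjusted p = 7.56e-06), with the protease CTSS up 3.43-fold and the sphingolipid activator PSAP 4.6-fold. NRF2 targets had 10 higher, 2 lower and 15 not passed (12 adjusted over the list alone; adjusted p = 0.00265), with the quinone reductase NQO1 up 2.69-fold. Hypoxia and glycolysis genes had 16 higher, 8 lower and 11 not passed (25 adjusted over the list alone; adjusted p = 0.0101), with the glucose transporter SLC2A3 up 8.62-fold and the repressor BHLHE40 6.24-fold. TGF-beta and activin genes had 14 higher, 4 lower and 13 not passed (18 adjusted over the list alone; adjusted p = 0.000386, and adjusted p = 0.181 with an estimated correlation). THBS1, a matrix protein that activates TGF-beta, rose 509-fold, and ACVR2A, an activin receptor, 4.79-fold. Apoptosis and p53 targets had 15 higher, 7 lower and 10 not passed (22 adjusted over the list alone; adjusted p = 0.00533, and adjusted p = 0.126 with an estimated correlation), with the growth suppressor BTG2 up 19.8-fold.

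All 43 ribosomal protein genes, whose reads can also match their pseudogenes, were lower (43 adjusted over the list alone; median -0.58, adjusted p = 4.61e-16, and adjusted p = 0.242 with an estimated correlation), among them RPS2 at -0.88 ± 0.05 and RPL3 at -0.84 ± 0.07. Oxidative phosphorylation had 3 higher, 24 lower and 13 not passed (29 adjusted over the list alone; adjusted p = 0.00242, and adjusted p = 0.557 with an estimated correlation), with the complex I subunit NDUFB10 at -0.74 ± 0.06. Of 13 mitochondrially encoded transcripts 8 were lower and 5 not passed (8 adjusted over the list alone; adjusted p = 0.0394, and adjusted p = 0.557 with an estimated correlation). This call was lost without NC 2, LPS 1 or LPS 2 and with relative log expression or upper quartile factors (adjusted p 0.0112 to 0.109 over the alternatives).

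Among lists whose test did not pass, calcineurin and NFAT genes had 5 higher, 3 lower and 7 not passed (9 adjusted over the list alone). Their test, at an adjusted p of 0.123, passed in 5 of 17 alternatives (0.00543 to 0.323). RCAN1, a calcineurin regulator that calcineurin itself induces, rose 22.5-fold to 396 ± 14.2 CPM. Iron and heme genes had 7 higher, 8 lower and 13 not passed (16 adjusted over the list alone), with a median of -0.05 and a mean of 0.37. That list passed in 2 of 17 alternatives (adjusted p 0.0249 to 0.997). The ferritin heavy chain FTH1, whose reads can also match its pseudogenes, rose 23.3-fold, and heme oxygenase (HMOX1) rose 53.9-fold. The cell cycle list had 8 higher, 9 lower and 23 not passed (16 adjusted over the list alone), with the kinetochore gene CENPF at 0.76 ± 0.07 and the replication helicase MCM3 at -0.68 ± 0.05. Protein stress genes had 12 higher, 11 lower and 11 not passed (24 adjusted over the list alone), with a median of 0.22 and a test pointing down (adjusted p = 0.941). ATF3, a stress transcription factor, rose 7-fold, and the serine synthesis gene PSAT1 fell 2.83-fold. Cholesterol synthesis had 3 higher, 7 lower and 14 not passed (10 adjusted over the list alone), with the sterol carrier STARD4 up 2.34-fold. Of 12 tested histone genes 0 were higher, 0 lower and 12 not passed (0 adjusted over the list alone), and these transcripts were raised in NC 3 and LPS 1, the libraries with the most ribosomal RNA.

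Markers of other cell types were at or near 0 with a few exceptions. Of 5 tested fibroblast, epithelial and endothelial markers 4 were higher and 1 lower (5 adjusted over the list alone; adjusted p = 4.44e-05). That call was lost with no low-count filter, where the median was -0.26 (adjusted p 3.93e-06 to 0.14 over the alternatives). The matrix proteoglycan DCN had 2376 counts in LPS and 3 in NC, a ratio of 781 (267 to 3790), and its neighbour LUM 2245 and 2, a ratio of 1110 (306 to 9140). PDGFRA, a growth factor receptor, rose 25.9-fold. Collagens stayed low, with COL1A1 at 0.05 CPM and COL1A2 at 0.02 CPM before scaling in LPS. Of 5 lymphocyte markers 3 were higher and 2 lower (5 adjusted over the list alone; the list's test did not pass, adjusted p = 0.274), with the T cell receptor gene TRAC up 55.5-fold to 7.41 ± 0.439 CPM. Of 21 erythroid and megakaryocyte markers 2 could be tested, so the list was not. The erythropoietin receptor EPOR had 2.67 CPM before scaling in NC and 1.42 in LPS. PPBP, added after its values were seen, went the other way, with 0.06 and 0.95 CPM before scaling. Of the 14 lists that changed in LPS, 11 up and 3 down, 9 held with an estimated correlation. Their adjusted p was then 0.000124, for the interferon list among others, to 0.0427, for TLR4 signalling.

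CE was compared with LPS to ask what cyclosporin A with eltrombopag does in the model. RCAN1, the calcineurin-induced regulator, fell 36.3-fold (-5.18 ± 0.12) from 396 ± 14.2 to 10.9 ± 2 CPM. HSD11B1, which regenerates active cortisol, fell 34.8-fold, and S100A8 fell 26.8-fold from 475 ± 19 to 17.7 ± 1.32 CPM. IL1B did not pass at -0.2 ± 0.08 (adjusted p = 0.0747; 0.00203 to 0.569 over 22 alternatives, of which 8 passed), with 1740 ± 174 CPM in CE and 1990 ± 106 in LPS. NLRP3 rose 2.55-fold (1.35 ± 0.05) to 270 ± 12.8 CPM, and hypoxia and glycolysis genes rose, 28 of 35.

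The cytokines went different ways. IL6 fell 4.03-fold to 0.84 ± 0.19 CPM, TNF rose 1.75-fold to 121 ± 25.3 CPM and IL18 rose 1.89-fold to 22.6 ± 1.58 CPM. CE 2 raised the CE mean of TNF, with 3120 counts beside 2198 in CE 1 and 2171 in CE 3. IL1A fell by a small amount (-0.27 ± 0.08, adjusted p = 0.0168), a call lost without LPS 1 or with no low-count filter (adjusted p 0.000202 to 0.406 over the alternatives). CXCL8 at -0.4 ± 0.12 (adjusted p = 0.0128) was lost without LPS 1 or LPS 2 (5.4e-05 to 0.137 over the alternatives). CASP1 (-0.09 ± 0.06, adjusted p = 0.212), PYCARD (0.32 ± 0.18, adjusted p = 0.168) and GSDMD (0.11 ± 0.82, adjusted p = 0.927, a direction that turns with scaling) did not pass.

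Other large falls were in CD93, a receptor on myeloid and endothelial cells (15-fold, from 55.7 ± 6.6 to 3.7 ± 2.72 CPM), MX1 (-3.52 ± 0.05, from 266 ± 6.26 to 23.1 ± 0.517 CPM) and the chemokine receptor CCR2 (11.1-fold). CE 2 held more CD93 than CE 1 and CE 3, and without it the change in CD93 was -4.69. Among genes with a mean log2 CPM of at least 3 and no overlap, the largest rises were in FCGR2B, the inhibitory IgG receptor (11-fold, to 46.6 ± 0.925 CPM), and CD300A, another inhibitory receptor (9.5-fold). TGM5 rose 8.73-fold, CREBRF, a regulator of metabolic stress, 8.68-fold, ZC3H12C, an RNase related to regnase, 8.19-fold, and KLHL24, a ubiquitin ligase adaptor, 7.55-fold. TGM5 went back to 25.9 ± 1.34 CPM, beside 25.1 ± 0.901 in NC. In total 4057 genes rose and 2915 fell, 996 and 1046 of them by at least 2-fold. The split depended on scaling, with 2945 higher and 4000 lower on upper quartile factors and 3040 and 3833 on library size alone. Limma on log2(FPKM + 1), which changes both the measure and the test, gave 2743 and 3516. Upper quartile factors and library size moved the median of all genes by -0.179 and -0.152, so small rises are relative to that shift. Groups did not overlap for 7684 genes (54.63%, against 10% by chance).

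Hypoxia and glycolysis genes had 28 higher, 2 lower and 5 not passed (30 adjusted over the list alone; median 0.89, adjusted p = 3.19e-11). The glycolytic enzymes ENO2 and ALDOC rose 10.9-fold and 7.38-fold, and the oxygen-sensitive demethylase KDM3A 2.98-fold. Protein stress genes had 17 higher, 6 lower and 11 not passed (25 adjusted over the list alone; adjusted p = 0.00184), with asparagine synthetase (ASNS) up 4.37-fold, the chaperone DNAJB9 4.07-fold and the stress factor DDIT3 3.05-fold. Lysosomal genes had 19 higher, 3 lower and 8 not passed (22 adjusted over the list alone; adjusted p = 0.000132, and adjusted p = 0.0707 with an estimated correlation), among them the proton pump subunit ATP6V1H (3.64-fold). The TGF-beta and activin list had 18 higher, 2 lower and 11 not passed (21 adjusted over the list alone; adjusted p = 0.00281, and adjusted p = 0.319 with an estimated correlation). SKIL, a repressor of SMAD signalling, rose 5.22-fold, the receptor TGFBR1 2.37-fold, and THBS1 fell 10.1-fold.

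Monocyte and macrophage markers fell, with 6 higher, 16 lower and 8 not passed (24 adjusted over the list alone; median -0.83, adjusted p = 5.29e-05; median -1.71 without CE 2). S100A9 fell 8.78-fold, the IgG receptor FCGR1A 5.3-fold and LYZ 5.12-fold. The cell cycle list had 2 higher, 21 lower and 17 not passed (24 adjusted over the list alone; adjusted p = 1.81e-06), including the mitotic kinesin KIF20A (-1.44 ± 0.08) and the nucleotide reductase RRM2 (-1.4 ± 0.06). Interferon genes had 10 higher, 20 lower and 16 not passed (32 adjusted over the list alone; adjusted p = 0.00281, and adjusted p = 0.252 with an estimated correlation), with IFI27 down 3.66-fold and IFI44L 2.08-fold. Of 5 fibroblast, epithelial and endothelial markers 2 were higher and 3 lower (5 adjusted over the list alone; adjusted p = 0.0201, and adjusted p = 0.167 with an estimated correlation). DCN fell 17.9-fold to 2.07 CPM and LUM 16.4-fold, while PECAM1, which monocytes also express, rose 1.7-fold. That list's call was lost without LPS 3, without CE 2, with the GC offset and with no low-count filter, where the median was 0.55 (adjusted p 0.000791 to 0.582 over the alternatives). Of the 8 lists that changed in CE, 4 up and 4 down, 4 held with an estimated correlation (adjusted p 0.000773 to 0.0364).

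The pyroptosis list did not pass, with 9 higher, 10 lower and 7 not passed (19 adjusted over the list alone). Its median was 0.04 and its mean -0.03, and the median turned to -0.14 on upper quartile factors and -0.1 on library size. Within it NAIP, a sensor of bacterial flagellin, fell 5.39-fold, and TXNIP, which binds NLRP3, rose 2.2-fold. NF-kB targets had 13 higher, 16 lower and 14 not passed (29 adjusted over the list alone), with a median of 0.06 that turned with scaling, a mean of -0.15 and a test pointing down (adjusted p = 0.396). The chemokine CCL8 fell 16.9-fold and CCL4 4.02-fold, while TNFAIP3, an inhibitor of NF-kB, rose 2.72-fold. TLR4 signalling had 11 higher, 3 lower and 7 not passed (14 adjusted over the list alone), and CD14 fell 6.83-fold. Calcineurin and NFAT genes had 7 higher, 3 lower and 5 not passed (11 adjusted over the list alone), with RCAN3, a relative of RCAN1, up 2.64-fold. Iron and heme genes had 9 higher, 8 lower and 11 not passed (17 adjusted over the list alone), and FTH1 rose 1.53-fold.

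Cholesterol synthesis had 11 higher, 4 lower and 9 not passed (15 adjusted over the list alone), with the epoxidase SQLE at 0.92 ± 0.04. Its test, at an adjusted p of 0.121, passed in 3 of 17 alternatives (0.0161 to 0.27). NRF2 targets had 13 higher, 3 lower and 11 not passed (16 adjusted over the list alone), with NFE2L2 itself at 1.08 ± 0.06. Their test, at an adjusted p of 0.108, passed in 5 of 17 alternatives (0.00252 to 0.239). Apoptosis and p53 targets had 13 higher, 4 lower and 15 not passed (17 adjusted over the list alone), and BTG2 fell 2.99-fold. That list passed in 1 of 17 alternatives (adjusted p 0.0268 to 0.46). Directions turned with scaling for oxidative phosphorylation (9 higher, 6 lower, 25 not passed, 15 adjusted over the list alone; NDUFB5 at 0.53 ± 0.08), for mitochondrially encoded transcripts (5, 2 and 6, with 7 adjusted over the list alone; MT-ND6 at 0.83 ± 0.11) and for ribosomal proteins (17, 2 and 24, with 19 adjusted over the list alone; RPL28 at 0.53 ± 0.07). Ribosomal proteins passed in 3 of 17 alternatives (adjusted p 0.00607 to 0.93). Histones had 0 higher, 3 lower and 9 not passed (1 adjusted over the list alone), with a median of -2 (-4.68 to 0 over the alternatives, of which 4 passed). LPS 1, high in ribosomal RNA, carries much of this, with H2BC18 at 16.6 CPM there, 0.237 and 0.444 in the other LPS libraries and 0.0481 to 0.148 in CE. Lymphocyte markers had 0 higher, 2 lower and 3 not passed (2 adjusted over the list alone), with TRAC down 4.31-fold.

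Of the genes changed by the model, 1721 changed the opposite way in CE, 701 from higher to lower and 1020 from lower to higher, where independence gives 653.3 and 953.6. In the model's direction 2347 changed further, 1397 of them higher in both (909.2 if independent) and 950 lower in both (685.2). Opposite and same-direction numbers thus both exceeded independence, so the excess of opposite changes does not by itself show reversal. At a 2-fold threshold the order turned, with 376 opposite (261 from higher to lower and 115 from lower to higher) and 336 in the same direction. The split of the opposite changes also turned to 895 and 760 on library size and 651 and 435 with no low-count filter. Both comparisons share the LPS libraries, which are too few to divide between them, so part of the opposite changes can come from the sharing. The covariance of the changes was -0.1221, against -0.0682 when only that sharing was simulated. The Pearson r was -0.096, against a mean of -0.497 in the simulation, and the Spearman rho was 0.09, of the other sign. Real effects also lower the size of r, so its distance from the simulated value does not measure a reversal. The simulation holds no effects, so it gives no number of opposite genes to expect here. Among genes raised by the model that fell in CE were IFI27, SLAMF7 (1.63-fold lower) and CCL4L2 (1.92-fold lower).

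**Figure D3:**
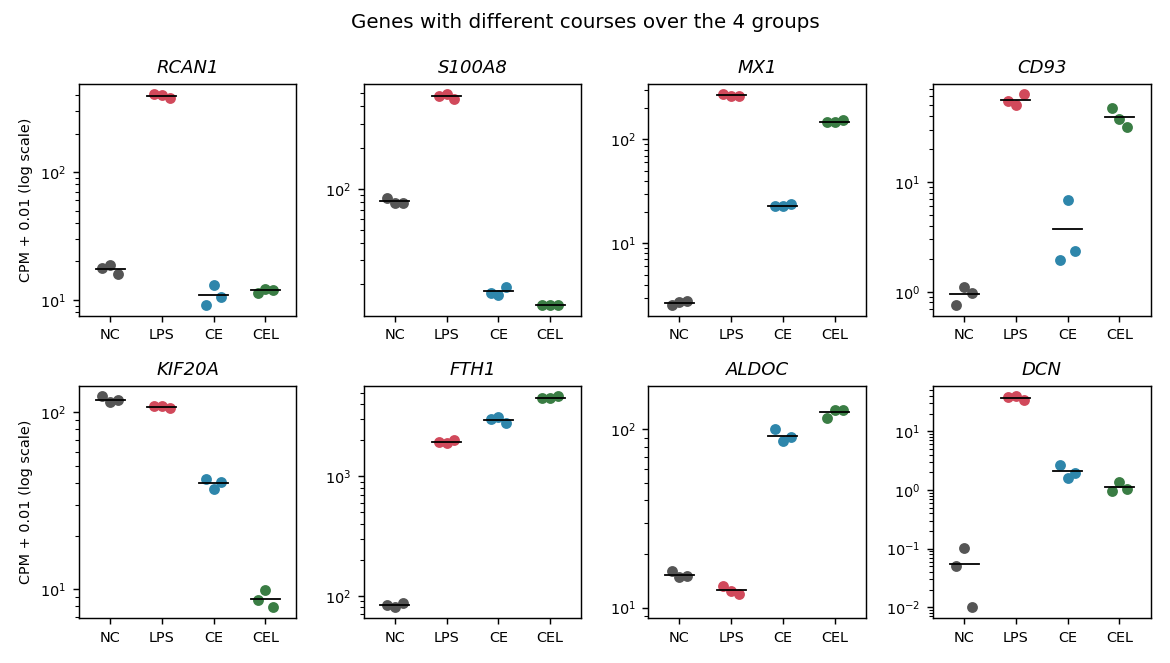
Levels of 8 genes (CPM + 0.01, log axis) in NC, LPS, CE and CEL, with 1 point per library and a horizontal line at the group mean. RCAN1 and S100A8 fall in CE and stay low in CEL, MX1 and CD93 fall in CE and are higher again in CEL (149 and 38.7 CPM), and KIF20A goes from 108 CPM in LPS to 39.7 and 8.84.

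CEL was compared with LPS to ask what the 3 drugs together do in the model. IL1B fell 1.85-fold (-0.89 ± 0.08, adjusted p = 3.71e-06) from 1990 ± 106 to 1080 ± 58.9 CPM. IL1A fell 1.88-fold, IL6 7.62-fold to 0.445 ± 0.0957 CPM, CXCL8 1.61-fold and CASP1 1.34-fold (-0.42 ± 0.06; lost with limma on TPM, adjusted p 2.55e-07 to 0.0737 over the alternatives). NLRP3 rose 2.38-fold to 253 ± 8.06 CPM, and IL18 rose 2.1-fold to 25.2 ± 3.59 CPM. TNF (-0.18 ± 0.14, adjusted p = 0.276), PYCARD (-0.22 ± 0.18, adjusted p = 0.333) and GSDMD (-0.7 ± 0.87, adjusted p = 0.529) did not pass. Among genes with a mean log2 CPM of at least 3 and no overlap, HSD11B1 fell 46.7-fold, S100A8 33.5-fold to 14.2 ± 0.097 CPM and RCAN1 33.5-fold, the largest falls together with CCR2 (22-fold), the protease inhibitor SERPINA1 (18.5-fold) and the membrane protein MS4A6A (17.5-fold). The largest rises among such genes were in FCGR2B (11.4-fold), ZC3H12C (11-fold), CREBRF (10.6-fold), the MAP kinase phosphatase DUSP10 (10.5-fold), CD300A (10.2-fold) and ALDOC (9.93-fold). In total 4039 genes rose and 3828 fell, 1226 and 1715 by at least 2-fold, and groups did not overlap for 9207 (65.46%, against 10% by chance). The majority turned with the setting, to 3294 higher and 4590 lower on upper quartile factors, 3381 and 4383 on library size, 3254 and 3975 with limma on FPKM and 3258 and 4441 with no low-count filter. Upper quartile factors and library size moved the median of all genes by -0.135 and -0.112.

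Cell cycle genes fell, with 2 higher, 31 lower and 7 not passed (33 adjusted over the list alone; median -0.82, adjusted p = 4.87e-17). KIF20A fell 12.2-fold, cyclin B1 (CCNB1) 6.65-fold, and the mitotic activator CDC20 5.31-fold. Hypoxia and glycolysis genes had 29 higher, 1 lower and 5 not passed (32 adjusted over the list alone; median 1.11), with ENO2 up 18.5-fold and BHLHE40 7.25-fold. Interferon genes had 5 higher, 28 lower and 13 not passed (35 adjusted over the list alone; adjusted p = 1.96e-07), with the interferon signal transducer STAT2 at -1.3 ± 0.06 and MX1 at -0.83 ± 0.04. Monocyte and macrophage markers had 6 higher, 14 lower and 10 not passed (20 adjusted over the list alone; adjusted p = 0.000849), including S100A9 (15.2-fold lower) and FCGR1A (8.63-fold lower). Lysosomal genes had 18 higher, 3 lower and 9 not passed (21 adjusted over the list alone; adjusted p = 1.84e-05), with the melanosomal glycoprotein GPNMB up 9.16-fold. Protein stress genes had 15 higher, 7 lower and 12 not passed (22 adjusted over the list alone; adjusted p = 0.0018), with ATF3 up 4.43-fold.

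TGF-beta and activin genes had 20 higher, 3 lower and 8 not passed (23 adjusted over the list alone; adjusted p = 0.000414, and adjusted p = 0.184 with an estimated correlation), with SKIL up 6.55-fold and ID2, a target of BMP signalling, 2.47-fold. Cholesterol synthesis had 10 higher, 3 lower and 11 not passed (13 adjusted over the list alone; adjusted p = 0.00475, and adjusted p = 0.103 with an estimated correlation), with SQLE up 2.38-fold. Fibroblast, epithelial and endothelial markers had 1 higher, 3 lower and 1 not passed (4 adjusted over the list alone; adjusted p = 0.0128, and adjusted p = 0.106 with an estimated correlation), with LUM down 34.3-fold and DCN 33.4-fold. This last call was lost without LPS 3, without CEL 3, with the GC offset and with no low-count filter, where the median was 1.29 (adjusted p 0.000946 to 0.668 over the alternatives). Of the 9 lists that changed in CEL against LPS, 5 up and 4 down, 6 held with an estimated correlation. Their adjusted p was then 0.000173 to 0.0458, the highest for the interferon and lysosome lists.

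The pyroptosis list did not pass, with 8 higher, 13 lower and 5 not passed (21 adjusted over the list alone; median -0.41, adjusted p = 0.492), NAIP down 8.4-fold and TXNIP up 3.08-fold. NF-kB targets had 13 higher, 18 lower and 12 not passed (31 adjusted over the list alone), with CCL8 down 56.9-fold and the apoptosis inhibitor BIRC3 up 4.34-fold. TLR4 signalling had 11 higher, 3 lower and 7 not passed (14 adjusted over the list alone), with CD14 down 16.3-fold. Calcineurin genes had 8 higher, 3 lower and 4 not passed (11 adjusted over the list alone). Iron and heme genes had 9 higher, 10 lower and 9 not passed (19 adjusted over the list alone), with FTH1 up 2.34-fold to 4570 CPM and the iron regulatory protein IREB2 down 1.45-fold. NRF2 targets had 11 higher, 4 lower and 12 not passed (15 adjusted over the list alone), with the malic enzyme ME1 up 3.35-fold and the reductase AKR1C3 down 3.26-fold. That list passed in 2 of 17 alternatives (adjusted p 0.0379 to 0.217). Apoptosis and p53 targets had 16 higher, 7 lower and 9 not passed (24 adjusted over the list alone), with the stress gene GADD45B up 3.52-fold. Oxidative phosphorylation had 9 higher, 9 lower and 22 not passed (18 adjusted over the list alone), and ribosomal proteins 8, 7 and 28 (14 adjusted over the list alone; RPL28 at 0.45 ± 0.07 and RPL3 at -0.68 ± 0.07, the call of RPL3 lost at adjusted p 0.0507 with the GC offset and replicate block). The direction of these 2 lists turned with scaling. Mitochondrially encoded transcripts had 3 higher, 4 lower and 6 not passed (7 adjusted over the list alone). Histones had 2 higher, 1 lower and 9 not passed (3 adjusted over the list alone), with a median of -0.51 and a test pointing up (adjusted p = 0.9). The median turned over the alternatives (-3.71 to 1.65) and depends on LPS 1, where H2BC9 had 3.29 CPM against 0.852 and 0.666 in the other LPS libraries. Lymphocyte markers had 0 higher, 2 lower and 3 not passed (3 adjusted over the list alone), with TRAC down 8.78-fold. Of the model's genes, 1761 changed the opposite way in CEL (864 from higher to lower, 857.9 if independent, and 897 from lower to higher, 949.4 if independent), and 2594 changed further in its direction, 1376 higher in both (905.1 if independent) and 1218 lower in both (899.8). At a 2-fold threshold 444 were opposite (344 from higher to lower and 100 from lower to higher) and 412 in the same direction. The split depends on the setting, with 977 and 770 on library size and 1034 and 333 with no low-count filter. The covariance was -0.1393, against -0.0676 from the shared libraries alone, while the Pearson r was -0.096 (a mean of -0.496 in the simulation) and the Spearman rho 0.06.

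CEL and CE differ by luspatercept alone, so this comparison asks what it adds. KIF20A, a kinesin needed for cytokinesis, fell 4.49-fold (-2.17 ± 0.08), from 39.7 ± 2.65 to 8.84 ± 0.99 CPM, and 28 of 40 cell cycle genes fell, KIF20A among them. IL1B fell 1.61-fold (-0.69 ± 0.08, adjusted p = 0.000175), from 1740 ± 174 to 1080 ± 58.9 CPM, IL1A fell 1.56-fold, and TNF fell 1.99-fold, from 121 ± 25.3 to 60.9 ± 3.05 CPM. The fall in TNF is enlarged by CE 2, with 3120 counts beside 2198 in CE 1 and 2171 in CE 3. MX1 rose 6.45-fold (2.69 ± 0.04), from 23.1 ± 0.517 to 149 ± 3.75 CPM, against the direction of most interferon genes.

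CASP1 fell 1.25-fold (-0.33 ± 0.06, adjusted p = 0.00198), a call lost without CE 1, CE 3, CEL 1 or CEL 2 (adjusted p 3.14e-05 to 0.595 over the alternatives). PYCARD did not pass (-0.55 ± 0.18, adjusted p = 0.0526), though it did with the replicate number as a block (0.0198 to 0.466 over the alternatives). NLRP3 (-0.1 ± 0.05, adjusted p = 0.162), IL18 (0.16 ± 0.1, adjusted p = 0.311), IL6 (-0.92 ± 0.33, adjusted p = 0.0667), CXCL8 (-0.28 ± 0.12, adjusted p = 0.107) and GSDMD (-0.81 ± 0.87, adjusted p = 0.552) did not pass. The other large rises were in CD93 (10.4-fold, to 38.7 ± 7.58 CPM), the protease inhibitor SERPINE2 (7.77-fold), the vesicle GTPase RAB13 (3.87-fold), GADD45B (3.64-fold) and IFI27 (3.13-fold). Without CE 2 the change in CD93 was 4.17 in place of 3.38 ± 0.38. Other large falls were in the hyaluronan receptor HMMR, which acts at the spindle (4.06-fold), the spindle gene PSRC1 (3.66-fold), the Cdc42 exchange factor FGD4 (3.6-fold), the relaxin receptor RXFP1 (3.27-fold) and the noncoding RNA CCDC26 (3.19-fold).

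In total 1235 genes rose and 2086 fell, 125 and 348 by at least 2-fold, and groups did not overlap for 4876 (34.67%, against 10% by chance). The split was 1581 and 1756 on library size, 1404 and 1274 with limma on FPKM, and 463 and 2075 with no low-count filter. It was 1685 and 1367 without CE 1, 1110 and 1145 without CE 3, 1023 and 1142 without CEL 1 and 1022 and 1098 without CEL 2. Most changes below 2-fold named here, IL1B and IL1A included, did not pass with limma on log2(TPM + 1), where 266 genes passed (adjusted p 4.26e-08 to 0.106 for IL1B over the alternatives).

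The cell cycle list had 0 higher, 28 lower and 12 not passed (28 adjusted over the list alone; median -0.55, adjusted p = 1.05e-26), with CCNB1 down 2.93-fold, CDC20 2.57-fold and the checkpoint kinase BUB1B 2.04-fold. Hypoxia and glycolysis genes had 19 higher, 0 lower and 16 not passed (19 adjusted over the list alone; median 0.32, adjusted p = 7.92e-13), among them the collagen hydroxylase P4HA2 (1.84-fold) and the mitophagy receptor BNIP3L (1.69-fold). Interferon genes had 3 higher, 29 lower and 14 not passed (36 adjusted over the list alone; median -0.47, adjusted p = 1.36e-09), with the chemokine CXCL10 down 2.16-fold and STAT2 1.68-fold. These 3 lists held with an estimated correlation, with interferon close to the threshold. The adjusted p was then 0.000377 for cell cycle, 0.000377 for hypoxia and glycolysis and 0.0467 for interferon genes.

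The pyroptosis list fell, with 2 higher, 9 lower and 15 not passed (13 adjusted over the list alone; median -0.28, adjusted p = 0.0187, and adjusted p = 0.274 with an estimated correlation). Its call was lost without CE 1 or CEL 1 (adjusted p 3.18e-05 to 0.111 over the alternatives). The inflammasome sensor NLRC4 fell 1.97-fold, to 16.3 CPM, and the ATP-gated channel P2RX7 1.97-fold, to 5.3 CPM. TGF-beta and activin genes had 7 higher, 4 lower and 20 not passed (11 adjusted over the list alone; median 0.18, adjusted p = 0.0226, and adjusted p = 0.546 with an estimated correlation). ID2 rose 1.63-fold and SMAD5, which carries BMP signals, 1.37-fold, and the repressor TGIF1 fell 1.48-fold. The list's call was lost without CE 1 or CEL 1 and with no low-count filter (adjusted p 0.00435 to 0.111 over the alternatives). Cholesterol synthesis had 9 higher, 2 lower and 13 not passed (12 adjusted over the list alone; median 0.15, mean -0.03, adjusted p = 0.000819, and adjusted p = 0.0912 with an estimated correlation), with INSIG1, a sterol sensor, up 1.4-fold. Lysosomal genes had 9 higher, 3 lower and 18 not passed (12 adjusted over the list alone; adjusted p = 0.0127, and adjusted p = 0.274 with an estimated correlation), with GPNMB up 2.21-fold. That call was lost with no low-count filter (0.00337 to 0.379 over the alternatives).

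Ribosomal proteins had 0 higher, 6 lower and 37 not passed (6 adjusted over the list alone; median -0.15, adjusted p = 0.00526, and adjusted p = 0.691 with an estimated correlation). The call was lost without CE 1, where the median was 0, without CE 3 or CEL 1 and with relative log expression factors (adjusted p 3.62e-10 to 0.859 over the alternatives). Histones had 2 higher, 0 lower and 10 not passed (2 adjusted over the list alone; median 1.88, adjusted p = 0.00619, and adjusted p = 0.691 with an estimated correlation), with H2AC6 up 5.28-fold to 7.45 CPM. The histone call was lost without CE 1, CE 2, CE 3, CEL 1 or CEL 2, and the median fell to 0.99 without CEL 3 (adjusted p 1.93e-08 to 0.117 over the alternatives). Of the 9 lists that changed between CEL and CE, 5 went up and 4 down.

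Among lists that did not pass, iron and heme genes had 5 higher, 6 lower and 17 not passed (11 adjusted over the list alone), with a median of -0.13 and a test pointing up. HMOX1 rose 2.78-fold to 43.5 CPM, FTH1 rose 1.53-fold and the ferric reductase CYBRD1 fell 1.5-fold (lost with limma on TPM + 0.1, adjusted p 0.572). NF-kB targets had 6 higher, 10 lower and 27 not passed (18 adjusted over the list alone), with the chemokines CXCL1 and CCL2 down 3.08-fold and 2.22-fold. That list passed in 1 of 17 alternatives (adjusted p 0.00659 to 0.815). TLR4 signalling had 2 higher, 4 lower and 15 not passed (6 adjusted over the list alone), with CD14 down 2.39-fold and the inhibitor IRAK3 1.72-fold. Monocyte and macrophage markers had 4 higher, 8 lower and 18 not passed (15 adjusted over the list alone), with the proteoglycan VCAN down 2.08-fold. Calcineurin genes had 1 higher, 1 lower and 13 not passed (2 adjusted over the list alone; median -0.04, mean 0.07), with the nuclear receptor NR4A2 up 2.92-fold. NRF2 targets had 5 higher, 4 lower and 18 not passed (10 adjusted over the list alone; median -0.23, test pointing up), with AKR1C2 down 1.93-fold. Protein stress genes had 4 higher, 4 lower and 26 not passed (9 adjusted over the list alone; median -0.05, test pointing up), with ASNS at -0.52 ± 0.07.

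Apoptosis and p53 targets had 9 higher, 5 lower and 18 not passed (14 adjusted over the list alone), with the death ligand TNFSF10 at -0.69 ± 0.08. That list, at an adjusted p of 0.0716, passed in 6 of 17 alternatives (0.0239 to 0.559). Mitochondrially encoded transcripts had 1 higher, 6 lower and 6 not passed (8 adjusted over the list alone). Their test, at an adjusted p of 0.0716, passed in 6 of 17 alternatives (0.00013 to 0.494). Oxidative phosphorylation had 0 higher, 1 lower and 39 not passed (0 adjusted over the list alone), with a direction that turned with scaling. It passed in 1 of 17 alternatives (adjusted p 0.0157 to 0.967). Lymphocyte markers had 1 higher, 1 lower and 3 not passed (3 adjusted over the list alone), and fibroblast, epithelial and endothelial markers 1, 3 and 1 (5 adjusted over the list alone), with DCN at 1.11 ± 0.214 CPM in CEL. Of the model's genes, 876 changed the opposite way between CEL and CE, comparisons that share no library. Of these, 639 went from higher to lower, where independence gives 467.5, and 237 from lower to higher, where it gives 290.3. A further 1248 changed in the model's direction, 508 of them higher (276.8 if independent) and 740 lower (490.3). With no low-count filter the order turned, to 753 opposite (716 and 37) and 517 in the model's direction, and upper quartile factors split the opposite ones into 485 and 429.

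**Figure D4:**
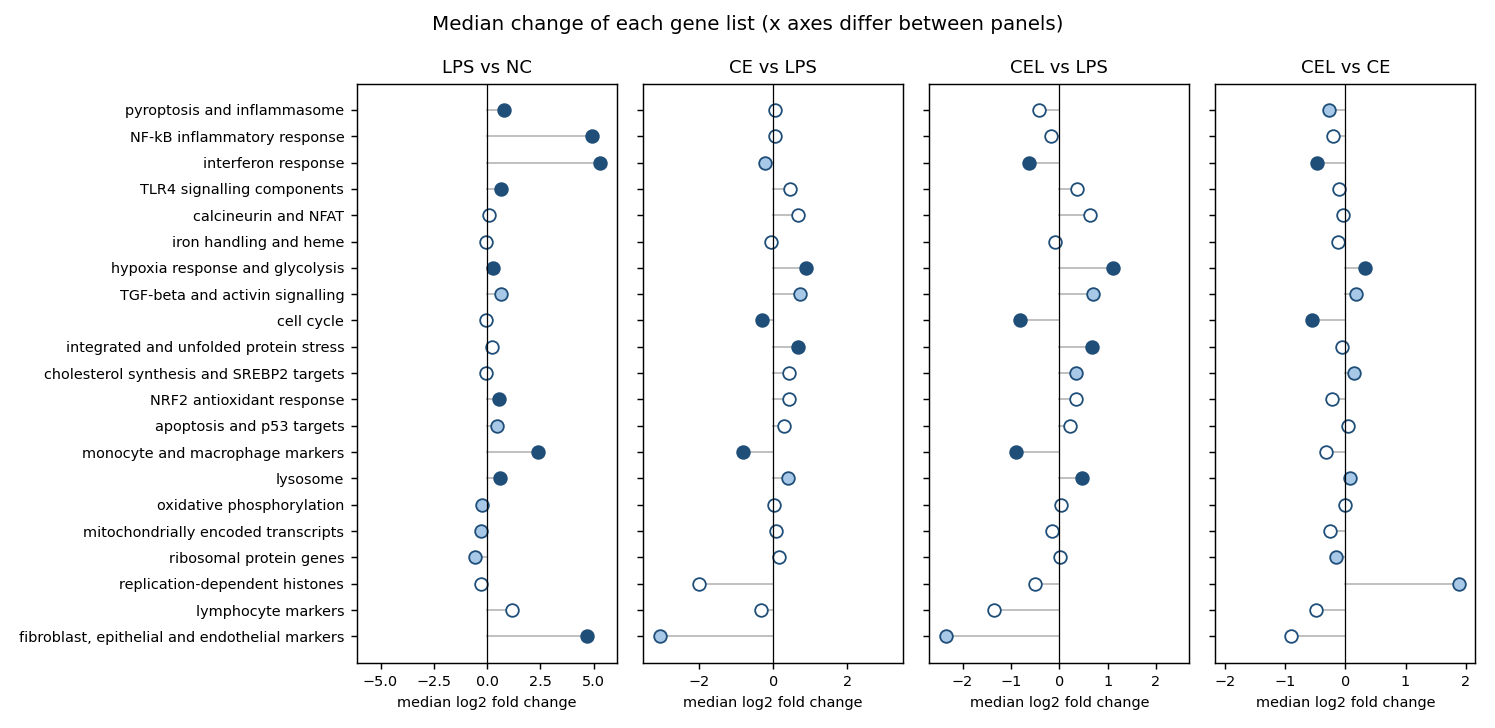
Median log2 change of each of the 21 tested lists (horizontal axis) in the 4 comparisons, with dark fill where the camera test passed with preset and estimated correlation, light fill where it passed with the preset one only and white where it did not pass. Cell cycle goes from -0.06 in LPS vs NC to -0.82 in CEL vs LPS, hypoxia and glycolysis rise in all 4 comparisons (0.28 to 1.11), and in CE vs LPS the signs of the pyroptosis, NF-kB, oxidative phosphorylation, mitochondrial and ribosomal protein lists turn with scaling, as do oxidative phosphorylation and ribosomal proteins in CEL vs LPS and oxidative phosphorylation in CEL vs CE.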

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

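The GC offset, alone and with the replicate block, and the fits without NC 3 and LPS 1 or without LPS 3, CE 2 and CEL 1 were tests chosen after the results were seen. Of the counts of changed genes, changed lists and genes changed in opposite directions, 199 stayed within 1.5 times the reported value and 32 were lower. None was higher by more than that factor, which lists in CE vs LPS with no low-count filter reached, at 12 against 8. A 2-fold threshold, which by construction keeps fewer genes, left 2320, 2042, 2941 and 473 genes in LPS vs NC, CE vs LPS, CEL vs LPS and CEL vs CE, and 376, 444 and 109 genes changed opposite to the model in CE, in CEL and between them. An adjusted p under 0.01 left 1999 in CEL vs CE. On limma with log2(TPM + 1) the same 4 comparisons gave 2963, 3586, 4984 and 266 genes, and with log2(TPM + 0.1) 2951, 3545, 4978 and 225. With log2(FPKM + 1) limma gave 5828, 6259, 7229 and 2678. FPKM and TPM are nearly proportional within a library, so the lower numbers on TPM go with the scale of each library. Why that scale lowers them was not tested. DESeq2 on the counts gave 5759, 6365, 7380 and 2787. With an estimated correlation 9 lists in LPS vs NC, 4 in CE vs LPS and 3 in CEL vs CE passed.

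Fits with fewer samples moved counts too. Without NC 3 and LPS 1, 4305 genes passed in LPS vs NC and 2096 in CEL vs CE, and 1026, 1101 and 436 changed opposite to the model. A fit of only the 6 libraries gave 1710 genes in CEL vs CE. With no low-count filter 1086 genes changed opposite to the model in CE (the cause was not tested). Leaving out 1 library at a time gave 5374 to 5795 genes in LPS vs NC, 6035 to 8123 in CE vs LPS, 7065 to 7366 in CEL vs LPS and 2120 to 4066 in CEL vs CE. The lowest value in CEL vs CE was without CEL 2, followed by 2165 without CEL 1, and the highest was without CE 2. Lists ranged over 13 to 15, 8 to 9, 8 to 9 and 5 to 10, with 5 in CEL vs CE without CEL 1. Genes opposite to the model ranged over 1313 to 2232, 1416 to 1614 and 507 to 1051, and the last was 547 without CE 3, 528 without CEL 1 and 507 without CEL 2.

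Single lists stayed on their side of the threshold in 1334 cases, lost a call in 34 and gained one in 39. The sign of the median turned in 84 of 1409 cases, in 80 of them without a pass in either fit. The direction of the test turned beside a pass in 2, the fibroblast, epithelial and endothelial markers in CEL vs LPS with no low-count filter (median 1.29) and ribosomal proteins in CEL vs CE without CE 1 (median 0, against -0.22 without CE 2; the cause was not tested). For named genes, 8560 cases stayed, 409 lost a call, of which 92 and 94 with limma on TPM, and 60 gained one. The sign turned in 22 of 9029 cases, none with a pass in either fit. The replicate block moved no count by 1.5 times. It ended the calls of H2BC18 in CE vs LPS and of FKBP1A, NDUFV1, CD79B and CCL4L2 in CEL vs CE, and it let PYCARD pass there, and no other named gene changed its call with it. Low counts limit GSDMD, at 2 to 27 per library, and IL6 and IL1A in NC, at 0 to 1 and at 2. GSDMD also varied between replicates, with 21 counts in LPS 3 beside 5 and 6. CE 2 held 27 beside 3 and 3, and CEL 1 held 11 beside 6 and 2. LPS 3, CE 2 and CEL 1 are described below as deviating together from their groups. The cause for GSDMD was not tested.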

Other observations

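The lists of ribosome biogenesis, MHC class II, heat shock, mitosis and DNA replication genes and their tests, the tests of depth, batch number, poly(A) selection, exchanged labels, fibroblasts, T cells and a stray sample, and the genes below outside the naming rule were chosen after the results were seen. The p of such a list comes from the values that led to it, so it is not independent evidence. Ribosome biogenesis genes fell in CE against LPS, with 24 of 29 lower, 0 higher and 5 not passed (25 adjusted over the list alone; median -0.67, camera adjusted p = 4.37e-12 over these 5 lists, and adjusted p = 0.00588 with an estimated correlation). The nucleolar genes NOP56 and NOP16 fell by 1.63 and 1.56 on the log2 scale, and nucleolin (NCL) fell from 1910 to 1060 CPM. In CEL against LPS 27 were lower and 2 did not pass, and between CEL and CE 1 was higher, 2 lower and 26 not passed. In LPS against NC, 2 were higher, 11 lower and 16 not passed. Cytosolic and mitochondrial heat shock genes had 12 higher, 1 lower and 5 not passed in LPS against NC (median 0.34, adjusted p = 0.0643, which did not pass) and 0 higher, 14 lower and 4 not passed in CE against LPS (median -0.67, adjusted p = 1.29e-08, and adjusted p = 0.0135 with an estimated correlation). In CEL against LPS 1 was higher, 13 lower and 4 not passed. Between CEL and CE 3 were higher, 0 lower and 15 not passed, the other way (median 0.06, adjusted p = 0.023, and adjusted p = 0.208 with an estimated correlation). The chaperone HSPA8, whose reads can also match its pseudogenes, went from 4060 CPM in LPS to 1040 in CE (-1.97 ± 0.08), and the mitochondrial cochaperone HSPE1 from 332 to 183 CPM.

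MHC class II genes, which present antigen to T cells, rose in CE against LPS in 9 of 9 cases (9 adjusted over the list alone). The median change was 0.98 (adjusted p = 0.000215, and adjusted p = 0.0283 with an estimated correlation). HLA-DRA rose by 1.64 ± 0.1 to 48.4 CPM, and the invariant chain CD74 by 0.96 ± 0.05 to 245 CPM. In CEL against LPS 7 were higher, 0 lower and 2 not passed (median 0.66, adjusted p = 0.0253, and adjusted p = 0.131 with an estimated correlation). Between CEL and CE 0 were higher, 3 lower and 6 not passed (median -0.47, adjusted p = 0.0141, and adjusted p = 0.136 with an estimated correlation), with CD74 at 177 CPM in CEL. In LPS against NC 4 were higher, 1 lower and 4 not passed. Within the cell cycle list, genes of mitosis and of DNA replication were set apart once its fall between CEL and CE was known, so no p is given. In mitosis 19 of 20 were lower and 1 not passed (median -0.99), and in DNA replication 8 of 16 were lower and 8 not passed (median -0.32). The mitotic kinase AURKA went from 166 to 71.3 CPM and the replication licensing factor CDC6 from 75.2 to 55.4. The difference between these lists was not tested.

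DCN, LUM and PDGFRA, and TRAC, were higher in LPS than in NC. Fibroblasts would bring collagen, but the sum of COL1A1, COL1A2 and COL3A1 was 0.00213 of DCN in LPS, and T cells would bring CD3, whose 3 genes came to 0 of TRAC. A stray sample would sit in 1 library, but the highest LPS library held 1.1 times the DCN of the lowest, so the tables argue against each of these. In the DCN cluster on chromosome 12, EPYC (90963679 to 91005026) rose with DCN and LUM (91102629 to 91111831), from 0 to 162 counts, at least 53.2-fold. KERA (91050491 to 91057983), between EPYC and LUM, had 3 counts in NC and 1 in LPS, too few to be tested. Whether LPS and ATP, which were given together, induce these transcripts in THP-1 cells, as a biological explanation would have it, stays open.

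NC 3 and LPS 1 held more ribosomal RNA, 6.556% and 4.734% of counts at 3 loci on chromosome 21, against 0.019% to 0.043% in the other 10 libraries. Less complete selection of polyadenylated RNA would raise histone transcripts, which lack a poly(A) tail. Of 40 listed histone genes 12 passed the low-count filter, and these 12 were above their group's other libraries in both, with medians of 3.38 and 2.74. High counts in NC 3 and LPS 1 can help a gene pass that filter, so these values cannot decide the question. Less complete selection stays a candidate explanation. Exchanged labels are argued against by 1990 genes changed at least 2-fold in a fit without these libraries, of which 97.84% lay nearer NC in NC 3 and 97.74% nearer LPS in LPS 1. No biological explanation was tested.

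LPS 3, CE 2 and CEL 1 deviated from their groups in a shared way (r = 0.7, 0.68 and 0.89 across genes, which are not independent replicates). Depth is argued against, since CE 2 held the lowest total of its group, CEL 1 the highest and LPS 3 the middle one, so at most 1 lay at the same end, and so is the batch number, since the 3 carry 3 different numbers. GC content may contribute, with a Spearman rho of at least 0.35 between it and the deviation in each of the 3. The correlations were still at least 0.61 over 7366 genes once the fit on GC content was removed. GC content measured as 1 value per gene, from 1 transcript, thus did not account for the whole pattern. A bias that acts on parts of transcripts would not be removed by that fit, so GC bias as the whole cause is not excluded. What these libraries share stays open, and no biological explanation was tested.

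Less iron in the cells, since eltrombopag binds iron, was a hypothesis for the rise of the hypoxia and glycolysis list in CE against LPS. It would raise the transferrin receptor TFRC, whose transcript is stabilised at low iron, and TFRC rose by 0.34 ± 0.06 (adjusted p = 0.00101), from 593 ± 24.1 to 750 ± 60.5 CPM. A rise of that size may follow from other effects of the drugs, so the value leaves the hypothesis open.

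Each pair of groups of 3 allows 10 splits of its 6 libraries, too few for a share under 0.05. Every split but the real one mixes both groups on each side. A real effect then widens the spread within each side, so few genes can be called, and part of the group difference remains for the lists. The other splits are therefore not a setting without effect, and no conclusion is drawn from them. As many changed genes as in the real split came from 1 split, the real one, in LPS vs NC (6458, highest other 0), CE vs LPS (6972, highest other 0), CEL vs LPS (7867, highest other 0) and CEL vs CE (3321, highest other 1). Genes changed opposite to the model likewise came from 1 split each (1721, 1761 and 876, highest other 0). As many lists came from 1 split in LPS vs NC (14, highest other 13), 5 in CE vs LPS (8, highest other 9), 4 in CEL vs LPS (9, highest other 10) and 1 in CEL vs CE (9, highest other 7). Replicate numbers are parted in all 3 pairs by 4 of the 10 splits, the real one included, and the highest other value among these was 0 for genes in each comparison and 10, 9, 10 and 7 for lists, where other splits reached 13, 8, 10 and 7.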
